A study of Homo sapiens with 6 samples.

How the data were processed

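Total RNA was measured in L428 cells, an established human Hodgkin lymphoma line. The cells received an siRNA against BATF3 or a negative control siRNA by nucleofection, a form of electroporation. Each nucleofection used 3 µg of siRNA and the cells were cultured for 48 hours, per the labels' protocols. The labels give 3 arrays for each siRNA, 6 in all. Biotin-labelled cRNA was hybridised to Affymetrix PrimeView arrays, which read each transcript with sets of short probes. There was only 1 BATF3 siRNA condition, with no second BATF3 siRNA condition to set beside it. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

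The deposited table held 1 value per probe set and array on a log2 scale. The base of the logarithm was inferred from the range of the values and is not given in the sources used here. The submitters' processing notes name the affy package for R, with no version. The background correction, normalization and summarization steps are not given in the sources used here. Array medians lay between 6.24 and 6.32, and after sorting each array the values at any 1 rank spread by at most 0.148 (median 0.047). The 6 arrays therefore had closely similar but not identical distributions, and the log2 values were used as deposited. Normalization of this kind sets the arrays to a common scale, so a shift of most transcripts in 1 direction would not be seen. Pairs of arrays correlated across genes at 0.995 to 0.998, where genes are not independent replicates. No 2 arrays held identical values.

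The table held 49495 probe sets, of which 102 were controls. A single gene was listed for 45278 probe sets, several genes for 1333 and no gene for 2782. Gene symbols came from the platform annotation and were looked up by Entrez identifier in a RefSeq gene table of the GRCh38.p14 assembly. That table held 45208 of the probe sets' identifiers and changed 0 symbols. Where a gene had more than 1 probe set, as for 11825 genes, the probe set with the highest mean over the 6 arrays stood for it. This left 18244 genes. Probe sets with several genes or none entered only a test per probe set. No genomic coordinates are given, since the values carry no genome build.

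Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), as BATF3 siRNA minus control siRNA over the 6 arrays with no further covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05 with no minimum fold. Intervals are 95% confidence intervals from the same fit, which had 9.30 total degrees of freedom, 4 of them residual. The number of arrays limits the precision, and the median standard error of a log2 change was 0.107. Exact permutation tests of 3 arrays against 3 cannot give a two-sided p below 0.1.

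Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 29 lists. Camera asks whether the members of a list moved more than other genes. The same test with a correlation estimated per list was set beside it, as was fry, which asks whether the members move on balance in 1 direction without comparing them with other genes. The lists covered the AP-1 and BATF family, the IRF family, the MYC network and MYC target genes, ribosomal proteins, S phase and G2/M phase genes. They also covered NF-kappaB, JAK-STAT, interferon, immediate early, ATF4, endoplasmic reticulum stress, heat shock and p53 genes, and B cell, plasma cell, Hodgkin lymphoma and MHC class I and II genes. The rest were cholesterol synthesis, glycolysis, hypoxia, oxidative phosphorylation, apoptosis regulators, RNA interference and the markers of 3 other cell types. A list member with no probe set of its own was not analysed here.

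The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named BATF3 and MYC, and up to 12 rises and 12 falls among called genes whose groups did not overlap. From each list it took up to 4 called members, or the 2 members with the smallest p where none was called. Genes named outside this rule are said to have been chosen after their values were seen. The alternatives covered normalization, filters on dim genes, the choice of probe set, array weights, an intensity trend with a robust prior, the replicate number as a block, other thresholds, Welch's test and leaving out each array. A term for array background was added after seeing the data.

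The fit was tested on simulated data with the spread of the real arrays, in which 200 of 18244 genes were changed. At a log2 change of 2 it recovered 70 of 70 genes, at 1 it recovered 62 of 73, and at 0.5 it recovered 23 of 57. Of 160 calls 5 were false. These rates hold for 200 changed genes with noise drawn independently for each gene and array. With fewer calls the Benjamini-Hochberg method demands a smaller p. The rates may therefore overstate recovery in the real data, where 3 genes were called. In simulated lists shifted by 0.3 on the log2 scale, 5 of 5 were called and 0 of the others. These lists held random genes with independent noise, so they cannot show how often camera calls lists of correlated genes. In the real data the estimated correlation was 0.19 for the ATF4 list, for example. The shift of 0.3 was also larger than the mean of any list called below, at most 0.26.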

Results

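Gene expression was compared in L428 cells, a line from human Hodgkin lymphoma, after an siRNA against BATF3 and after a negative control siRNA. BATF3 is a basic leucine zipper transcription factor that pairs with JUN proteins and with IRF factors. Expression was measured on 3 arrays per siRNA at 48 hours after nucleofection, as log2 values deposited by the authors, for 18244 genes. The comparison asks which transcripts changed when BATF3 was reduced. MYC was set out as a gene of interest because it was studied downstream of BATF3 in this disease.

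BATF3 mRNA was lower in all 3 BATF3 siRNA arrays than in all 3 control arrays, at 10.77 ± 0.088 against 11.97 ± 0.10 (log2, SD, n = 3 each). It fell by 1.20 on the log2 scale (SE 0.095), to 0.436 of the control level (95% confidence interval 0.376 to 0.506; limma adjusted p = 0.00673). BATF3 had 1 probe set. The separate two-sided exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Without BATF3 siRNA replicate 3 the adjusted p was 0.0688 and without control siRNA replicate 2 it was 0.0648, while the change was −1.16 and −1.14. Over the 17 alternative limma fits the adjusted p ran from 3.82e-05 to 0.306.

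Besides BATF3, 2 genes passed the threshold. CD244, which encodes a receptor of the SLAM family known from natural killer cells, fell by 1.39 (SE 0.12), to 0.382 of the control level in the deposited values (limma adjusted p = 0.00985; 7.19 ± 0.21 against 8.58 ± 0.13, SD, n = 3 each). Of its 3 probe sets, the other two changed by −1.02 and −0.0030. In BATF3 siRNA replicate 1 its level (6.98) lay under the highest background probe set of that array (7.18, with 25 G and C bases per probe). The background that applies depends on the bases of its probes, which were not examined, so the size of this fold is uncertain. MYO10, which encodes an unconventional myosin of filopodia, rose by 0.91 (SE 0.10), to 1.88 times the control level in the deposited values (limma adjusted p = 0.0468; 7.24 ± 0.10 against 6.33 ± 0.14, SD, n = 3 each). All 5 of its probe sets were higher, by 0.29 to 0.91. Its level lay under the highest background probe set of the same array in the 3 control arrays (7.11 to 7.32). The same held in BATF3 siRNA replicate 1 (7.13 against 7.18). The bases of the MYO10 probes were not examined either, so the size of this fold is uncertain. For both genes the 3 arrays of one siRNA lay on one side of the 3 of the other. The CD244 call was lost without BATF3 siRNA replicate 1 (adjusted p = 0.0762), BATF3 siRNA replicate 3 (0.0830), control siRNA replicate 2 (0.130) or control siRNA replicate 3 (0.0545), within a range over the 17 alternative limma fits of 0.000815 to 0.180. The settings that ended the MYO10 call included leaving out any 1 of the 6 arrays, quantile normalization (0.0612), median centring (0.0604), cyclic loess (0.0563) and averaging of probe sets (0.119), within a range over the same fits of 0.00547 to 0.769.

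MYC mRNA, which encodes a transcription factor of growth and ribosome production, did not pass the threshold. Its level was 10.64 ± 0.047 after BATF3 siRNA and 10.77 ± 0.052 after control siRNA (log2, SD, n = 3 each), a change of −0.13 (SE 0.084; limma adjusted p = 0.822). The ratio was 0.915, with a 95% confidence interval on the log2 scale of −0.32 to 0.062. The 3 BATF3 siRNA arrays lay below the 3 control arrays, and the two-sided exact permutation test gave the smallest possible p = 0.1. Of the 57 measured MYC target genes, which serve nucleolar and growth functions, 0 passed the threshold and 27 had a positive change (mean −0.015, or 0.0063 after median centring; camera adjusted p = 0.662). The list mean lay between −0.083 and 0.045 in the BATF3 siRNA arrays and between −0.084 and 0.12 in the control arrays. Its members with the smallest p were DUSP2 at +0.37 and MCM5 at −0.33. In the MYC network of partners and antagonists 0 of 13 genes passed (mean −0.024, adjusted p = 0.637), with MXD1 at +0.32 and MYCN at −0.29.

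**Figure D1:**
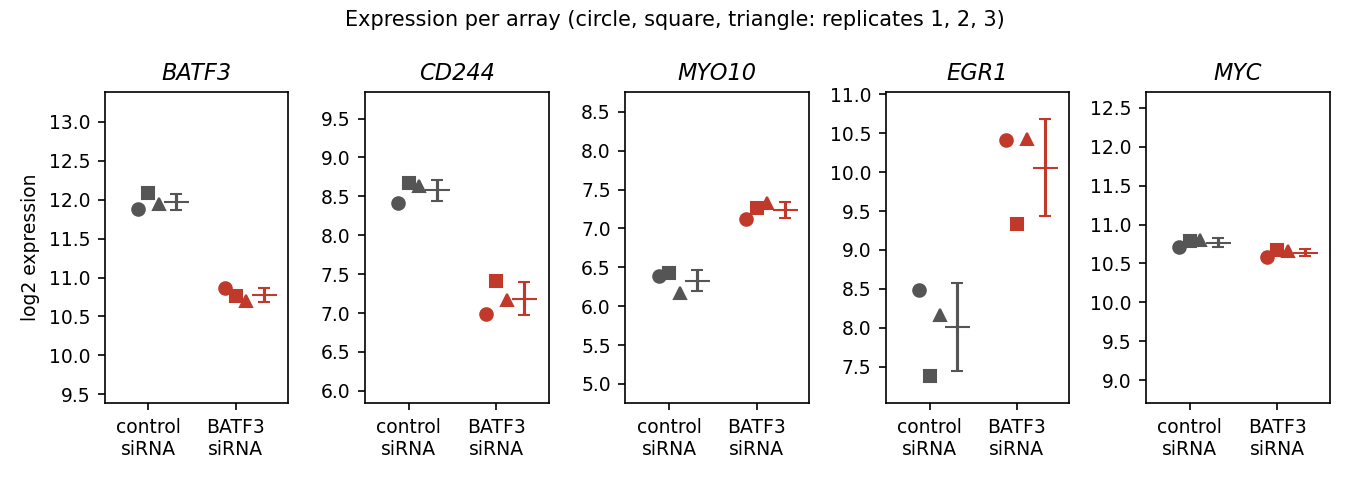
Log2 expression of 5 genes in each of the 6 arrays, with control siRNA in grey, BATF3 siRNA in red and bars for the mean ± SD; each panel spans the same range of log2 units. BATF3 and CD244 lie lower and MYO10 and EGR1 higher in all 3 BATF3 siRNA arrays, while MYC differs by −0.13.

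In total 3 of 18244 genes passed the threshold, 1 higher and 2 lower, and 6 had an adjusted p under 0.1. At an unadjusted p under 0.05 there were 1304 genes, 680 higher and 624 lower, where 912.2 would be reached by chance. The groups did not overlap for 2215 genes, or 12.1%, where chance gives 10%. Without BATF3 siRNA replicate 3 limma called 0 genes (852 at an unadjusted p under 0.05), and without control siRNA replicate 2 it also called 0 (1446 at an unadjusted p under 0.05). Without BATF3 siRNA replicate 1 it called 1 gene, BATF3, with 1929 at an unadjusted p under 0.05. Array weights called 25 genes (3312 at an unadjusted p under 0.05) and an intensity trend with a robust prior called 12, and all 3 genes were among them in both. The array weights were 0.91, 0.38 and 3.85 for control siRNA replicates 1, 2 and 3. In that fit the control mean thus rested mostly on replicate 3.

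**Figure D2:**
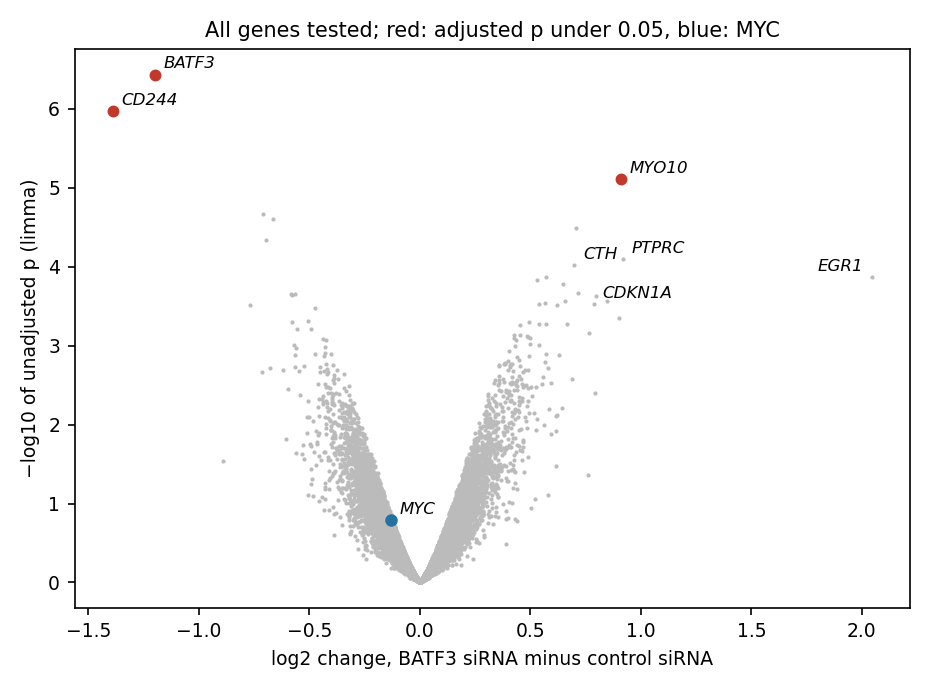
Log2 change (BATF3 siRNA minus control siRNA) against −log10 of the unadjusted limma p for all 18244 genes, with called genes in red and MYC in blue. BATF3, CD244 and MYO10 stand apart, and EGR1 has the widest change, +2.05, without passing the threshold.

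A technical measure moved in part with the siRNA. The array background probe sets rich in G and C bases (20 to 25 per probe) read 5.92 and 5.98 in BATF3 siRNA replicates 2 and 3, against 6.46 to 6.49 in the other 4 arrays, a difference of −0.53. BATF3 siRNA replicate 1 had the background of the controls. With this background as a block, a term added after seeing the data that leaves BATF3 siRNA replicate 1 against the controls, 0 genes passed in limma (1011 at an unadjusted p under 0.05). BATF3 was then at −1.10 (adjusted p = 0.306), CD244 at −1.59 (0.180) and MYO10 at +0.80 (0.769). In the same fit the 4 gene lists described next stayed called at the preset correlation, with means of 0.31 for immediate early genes (camera adjusted p = 1.33e-08), 0.24 for ATF4 target genes (8.88e-10), 0.12 for interferon-stimulated genes (0.00194) and 0.11 for NF-kappaB target genes (0.00457). Without the block, none of the 4 was called with an estimated correlation (adjusted p = 0.0632, 0.501, 0.416 and 0.504), and that test was not run with the block. The first principal component, 30.2% of the variance, set control siRNA replicate 2 apart from the other arrays. The second, 27.3%, put BATF3 siRNA replicates 2 and 3 at the far end from the controls 1 and 3 and BATF3 siRNA replicate 1.

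**Figure D3:**
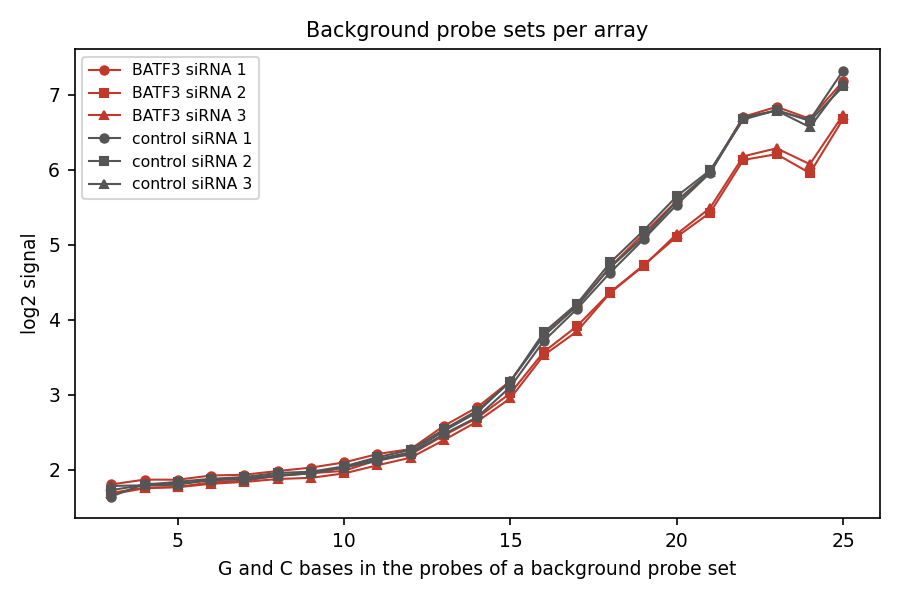
Log2 signal of the background probe sets in each of the 6 arrays, against the number of G and C bases in their probes. BATF3 siRNA replicates 2 and 3 lie below the other 4 arrays at 20 to 25 bases, by 0.53 on average.

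Immediate early genes, many of which cells switch on within minutes of growth factor or stress signals, were higher as a list after BATF3 siRNA (mean +0.26, median +0.23, 27 of 32 positive; camera adjusted p = 4.60e-10). With an estimated correlation the call was lost (adjusted p = 0.0632), and fry gave an adjusted p of 0.0393. Over all genes 0 members passed, and adjusted over the list alone 10 were higher and 0 lower. EGR1, a zinc finger transcription factor, stood at 10.06 ± 0.62 against 8.01 ± 0.57 (SD, n = 3 each), a change of +2.05 (SE 0.33; limma adjusted p = 0.221 over all genes). All 6 of its probe sets were higher, by 1.21 to 2.05. Its level was lowest in replicate 2 of both siRNAs (9.34 and 7.38), so part of the spread within each group may go with the replicate number. The settings under which it passed included an intensity trend and a robust prior (adjusted p = 0.0338) and array weights (0.0438), within a range over the 17 alternative limma fits of 0.000726 to 0.827. PHLDA1 was at +0.53 (SE 0.086; adjusted p = 0.221). The list mean was +0.31 in BATF3 siRNA replicate 1, whose background was that of the controls, and +0.20 and +0.29 in the other two, while the control arrays ran from −0.024 to 0.039.

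Target genes of ATF4 and the amino acid response, which include genes of amino acid synthesis and import and of stress responses, were also higher as a list (mean +0.18, median +0.098, 29 of 33 positive; camera adjusted p = 2.67e-09). The call was lost with an estimated correlation (adjusted p = 0.501), and the fry adjusted p was 0.155. Over all genes 0 members passed, and adjusted over the list alone 7 were higher (CTH, SLC7A11, SESN2, DDIT3, CEBPB, TRIB3 and CHAC1) and 0 lower. CTH, an enzyme that makes cysteine from cystathionine, was at +0.70 (SE 0.11; limma adjusted p = 0.193). SLC7A11, the cystine transporter, was at +0.48 (SE 0.098; adjusted p = 0.337). BATF3 siRNA replicate 1 had a list mean of +0.24 and replicates 2 and 3, with the lower background, had +0.10 and +0.19, against −0.027 to 0.030 in the controls.

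Interferon-stimulated genes had a mean of +0.095 and 37 of 46 positive changes (camera adjusted p = 0.000479, and adjusted p = 0.416 with an estimated correlation). OASL was at +0.41 and IFI44 at +0.29, both antiviral response genes. NF-kappaB target genes had a mean of +0.096 and 26 of 38 positive changes (camera adjusted p = 0.00261, and adjusted p = 0.504 with an estimated correlation). TNF, an inflammatory cytokine, was at +0.41 and BCL2A1, an inhibitor of apoptosis, at +0.40. In both lists 0 members passed over all genes or adjusted over the list alone, and the fry adjusted p was 0.155 and 0.278. The interferon list mean ran from 0.070 to 0.12 in the BATF3 siRNA arrays and from −0.027 to 0.047 in the controls. For NF-kappaB the ranges were 0.084 to 0.11 and −0.046 to 0.075, and without BATF3 siRNA replicate 1, the array with the background of the controls, the NF-kappaB call was lost (mean 0.087, adjusted p = 0.0761).

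**Figure D4:**
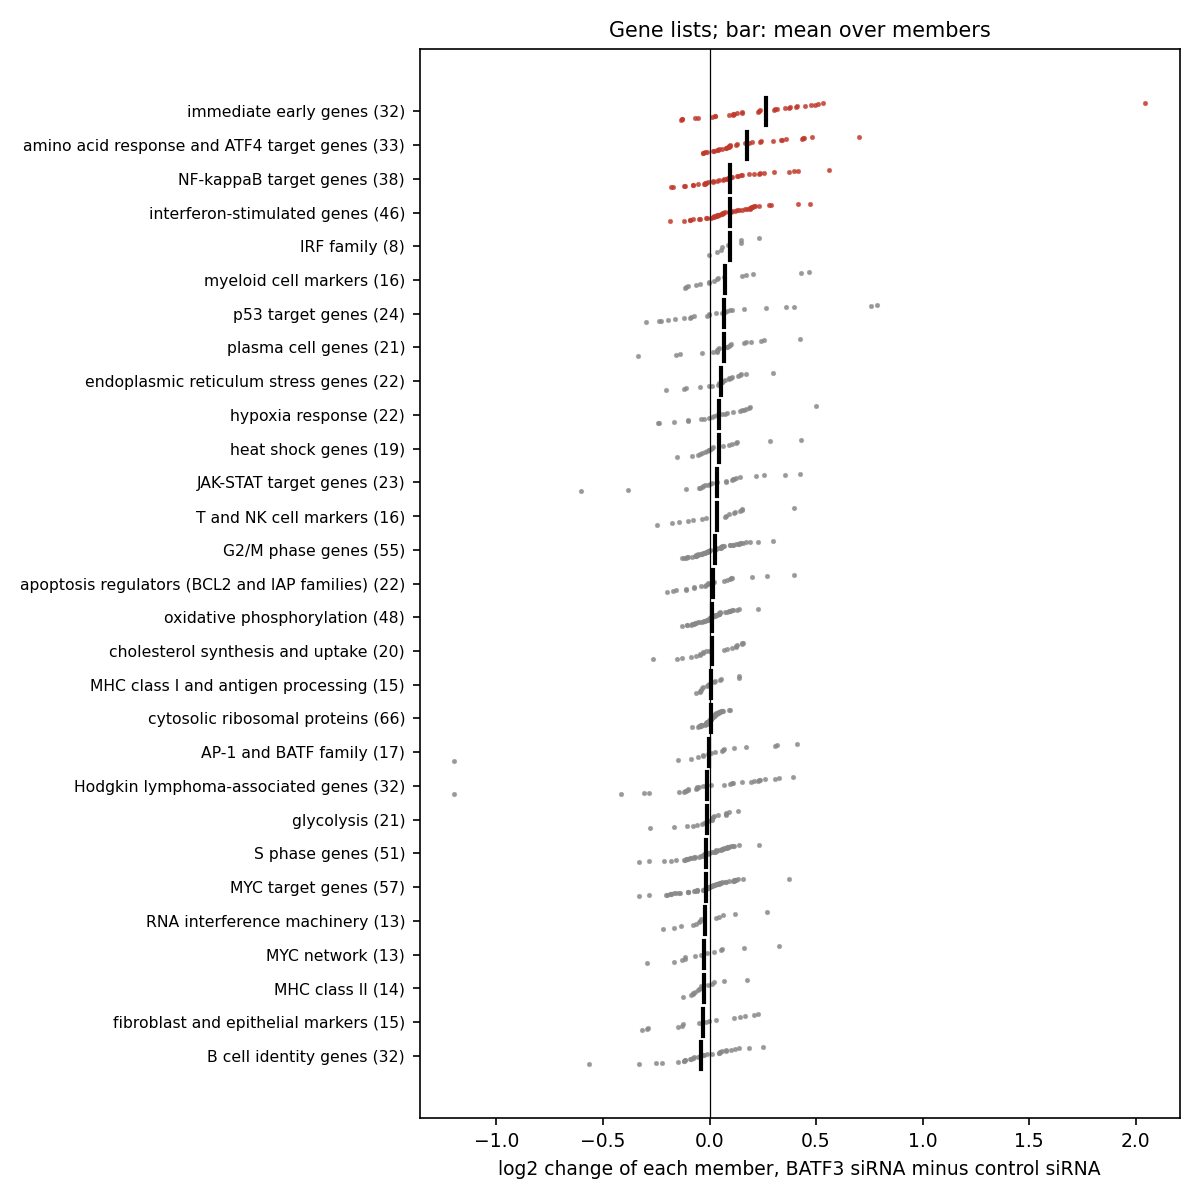
Log2 change (BATF3 siRNA minus control siRNA) of each measured member of the 29 gene lists, with the number of members in parentheses, a black bar for the list mean and red for lists with a camera adjusted p under 0.05. The 4 red lists are immediate early, ATF4, interferon-stimulated and NF-kappaB genes, with means from 0.095 to 0.26.

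None of the other 25 lists passed with camera at the preset correlation over all 6 arrays. Among 17 AP-1 and BATF family genes BATF3 alone was called, and adjusted over the list alone ATF3 also passed at +0.41. That list had a mean of −0.00086, which was positive under quantile normalization (0.0019), median centring (0.021) and cyclic loess (0.0041), a median of 0.026 and a camera direction of up (adjusted p = 0.662), so mean and test differed in sign. The IRF family, some members of which are partners of BATF proteins, had 7 of 8 positive changes and a mean of +0.094 (adjusted p = 0.114), with IRF9 at +0.23 and IRF1 at +0.15. JAK-STAT target genes had a mean of +0.034 (adjusted p = 0.492). Adjusted over the list alone the kinase gene PIM2 passed at +0.42 and STAT5B at −0.38.

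Of 32 genes known to be expressed in Hodgkin lymphoma, BATF3 alone was called. The mean was −0.0095 (0.012 after median centring) and the median −0.024, with a camera direction of up (adjusted p = 0.950). B cell identity genes had 13 of 32 positive changes and a mean of −0.042 (adjusted p = 0.581). BACH2, a transcription repressor of B cells, was at −0.57 and passed adjusted over the list alone, and POU2F2 was at −0.22. Both genes lay under the highest background probe set in every array. The bases of their probes were not examined, so the size of these changes is uncertain. Plasma cell genes had 17 of 21 positive changes and a mean of +0.068 (adjusted p = 0.0673), with PIM2 at +0.42 and JCHAIN at +0.24. They passed without BATF3 siRNA replicate 2 or control siRNA replicate 3, and over all alternatives the adjusted p ran from 0.0196 to 0.504. MHC class II genes had a mean of −0.025 (adjusted p = 0.662), with CTSS at +0.18 and CD1D at −0.12, where the CD1D change turned positive (0.011) for its most variable probe set. MHC class I genes had a mean of +0.0092 (−0.0064 under quantile normalization, −0.0035 under cyclic loess) and a median of −0.0055 (adjusted p = 0.847), with ERAP2 and TAP1 both at +0.14.

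Genes of S phase had a mean of −0.015, or 0.0064 after median centring (adjusted p = 0.662), with MCM5 at −0.33 and UNG at −0.28. For G2/M phase genes the mean was +0.027 (adjusted p = 0.453), with NUSAP1 at +0.30 and TTK at +0.23. Cytosolic ribosomal proteins had a mean of +0.0082 (adjusted p = 0.662), which turned to −0.017 under cyclic loess, with RPL27 at +0.092 and RPL3 at −0.083. Oxidative phosphorylation genes had a mean of +0.012, or −0.0061 under quantile normalization and −0.0091 under cyclic loess (adjusted p = 0.662), with NDUFB8 at +0.23 and NDUFB5 at +0.13. Glycolysis genes had a mean of −0.0095 (0.012 after median centring) and a median of 0.013 (adjusted p = 0.927), with PFKL at −0.28 and PFKFB4 at −0.17. Cholesterol genes had a mean of +0.011 (−0.0052 under quantile normalization, −0.0027 under cyclic loess) and a median of −0.0083 (adjusted p = 0.737), with TM7SF2 at −0.27 and HSD17B7 at +0.15. Hypoxia genes had a mean of +0.045 (adjusted p = 0.492), with ANKRD37 at −0.24 and EGLN3 at +0.17. The hypoxia mean was −0.12 in BATF3 siRNA replicate 2 and −0.16 in control siRNA replicate 2, against 0.060 to 0.13 in the other 4 arrays. Without BATF3 siRNA replicate 2 the list passed at the preset correlation (mean 0.13), and over all alternatives the adjusted p ran from 0.00573 to 0.991. With all 6 arrays and an estimated correlation (0.533) the adjusted p was 0.902.

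For p53 target genes the mean was +0.069 (adjusted p = 0.581). Of these CDKN1A, which encodes the cell cycle inhibitor p21, was at +0.79 (SE 0.14; limma adjusted p = 0.226) and GADD45A at +0.36, and both passed adjusted over the list alone. Endoplasmic reticulum stress genes had a mean of +0.054 (adjusted p = 0.257), with DNAJB9 at +0.30 and CRELD2 at −0.20. Heat shock genes had a mean of +0.045 (adjusted p = 0.590), with HSPA6 at +0.43 and CHORDC1 at +0.28. Apoptosis regulators had a mean of +0.017 and a median of −0.0060 (adjusted p = 0.662), with BCL2A1 at +0.40 and BMF at +0.27. The RNA interference machinery had a mean of −0.021, or 0.00011 after median centring (adjusted p = 0.662), with TNRC6A at +0.27 and DGCR8 at −0.22. Markers of other cell types had means of +0.033 for T and NK cells (adjusted p = 0.662), +0.072 for myeloid cells (0.453) and −0.032 for fibroblasts and epithelium (0.492). Their members with the smallest p were NKG7 at +0.40 and CD8A at −0.25, CD163 at +0.43 and CD68 at +0.47, and COL1A2 at −0.29 and KRT18 at −0.29. All of these but CD68 lay under the highest background probe set in every array, so the size of their changes is uncertain.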

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

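A probe set outside the gene-level comparison passed the threshold when all 49393 probe sets were tested one by one. Probe set 11716631_s_at, for which the annotation used here lists no gene, read 8.72 ± 0.33 after BATF3 siRNA and 7.18 ± 0.16 after control siRNA (log2, SD, n = 3 each). The change was 1.533 (SE 0.16; limma adjusted p = 0.0466), and all 3 BATF3 siRNA arrays lay above all 3 control arrays. In that test 5 probe sets passed, and the other 4 each had a single gene. The probe set that stood for MYO10 did not pass there (limma adjusted p = 0.0742). What 11716631_s_at measures was not settled, and no explanation was tested.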

How the results depend on the processing

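The number of arrays limits these results, as does the background. The highest background probe set, with 25 G and C bases per probe, read 6.68 to 7.32, above the array medians of 6.24 to 6.32. Background probe sets with 3 to 15 G and C bases averaged 2.06 to 2.20. Dim genes may thus lie within the background range, depending on the bases of their probes, which were not examined. Under the highest background probe set in every array lay CD163, CD1D, CD8A, COL1A2, EGLN3, HSPA6 and JCHAIN. So did KRT18, MCM5, MYCN, NKG7, OASL, IDO1 and CEP126, besides the genes for which this is stated above. The size of their changes is uncertain too. The term for array background was chosen after seeing the data, and log2(value + 16) was not run because the deposited values already were on a log scale. Where a result changed, the cause was not tested. The BATF3 change lay between −1.24 and −1.10 and the MYC change between −0.18 and −0.10 over 17 alternative limma fits, and MYC was called in none of them.

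For the count of called genes (3), 9 were called without the genes under the median level (4 higher, 5 lower), 5 with the most variable probe set (2 higher), 12 with an intensity trend and robust prior (5 higher, 7 lower) and 25 with array weights (15 higher, 10 lower). With the array background batch as a block 0 were called (0 higher, 0 lower), and Welch's test called 0 (0 higher, 0 lower; 844 at an unadjusted p under 0.05). Quantile normalization, median centring, cyclic loess, a minimum of 2-fold and an adjusted p under 0.01 each left 0 higher. Leaving out 1 array gave 0 to 2 genes, with 0 higher and 0 to 2 lower. BATF3 was at −1.10 with the background block and between −1.24 and −1.14 with 1 array left out. With the replicate block 3 genes were called, 2 of them shared (BATF3 and CD244) with EGR1 as the third (adjusted p = 0.000726), and MYO10 had an adjusted p of 0.108. Across all genes the numbers gave no clear pairing of the samples. Deviations of same-numbered arrays correlated at 0.029, 0.15 and −0.025, and 2 of 6 arrays correlated best with their own number. The value of 0.15, for both replicate 2 arrays, was the highest between any BATF3 siRNA and control array, ahead of 0.097. EGR1 was lowest in both replicate 2 arrays (9.34 and 7.38), as was the mean of the hypoxia list (−0.12 and −0.16). Variation shared by the replicate 2 arrays is therefore not excluded. The block changed no list call.

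With an estimated correlation 0 of 29 lists were called, where the immediate early mean is 0.26, ATF4 0.18, NF-kappaB 0.096 and interferon 0.095, and fry called 1 list, the immediate early genes, and not the ATF4 (0.18), NF-kappaB (0.096) or interferon (0.095) list. Leaving out 1 array gave 3 to 6 lists, with the NF-kappaB mean from 0.073 to 0.13. The MYC target mean was 0.0063 with median centring, 0.0099 with array weights and −0.057 to 0.044 with 1 array left out.

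Other lists, none called with all arrays, changed sign as follows. Quantile normalization gave 0.0019 for the AP-1 family, −0.0064 for MHC class I, −0.0052 for cholesterol and −0.0061 for oxidative phosphorylation. Median centring gave 0.021 for the AP-1 family, 0.0064 for S phase, 0.012 for Hodgkin lymphoma genes, 0.012 for glycolysis and 0.00011 for RNA interference. Cyclic loess gave 0.0041 for the AP-1 family, −0.0035 for MHC class I, −0.0027 for cholesterol, −0.0091 for oxidative phosphorylation and −0.017 for ribosomal proteins. The mean of all probe sets gave 0.039 for the AP-1 family, −0.0015 for oxidative phosphorylation and −0.0080 for T and NK cells. The most variable probe set gave 0.16 for the AP-1 family, −0.011 for oxidative phosphorylation, 0.016 for S phase, 0.00064 for Hodgkin lymphoma genes, 0.00047 for RNA interference, 0.016 for the MYC network and 0.019 for fibroblasts and epithelium. Array weights gave 0.0062 for the AP-1 family, −0.024 for cholesterol, −0.015 for hypoxia and −0.0056 for apoptosis. The background block gave 0.060 for the AP-1 family, 0.055 for Hodgkin lymphoma genes, 0.070 for glycolysis, 0.027 for RNA interference and 0.037 for the MYC network. Without members shared between lists the AP-1 family was at 0.0011, Hodgkin lymphoma genes at 0.015 and apoptosis at −0.0055, and without the genes under the median level B cell identity was at 0.013.

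With 1 array left out the list means ran from −0.031 to 0.032 for the AP-1 family, −0.016 to 0.038 for MHC class I, −0.023 to 0.063 for cholesterol, −0.00050 to 0.031 for oxidative phosphorylation and −0.028 to 0.0037 for S phase. They ran from −0.042 to 0.014 for Hodgkin lymphoma genes, −0.049 to 0.034 for glycolysis, −0.046 to 0.0066 for RNA interference, −0.0046 to 0.055 for T and NK cells and −0.017 to 0.050 for apoptosis. The ranges were −0.035 to 0.13 for hypoxia, −0.0012 to 0.069 for JAK-STAT and −0.041 to 0.00054 for MHC class II. Hypoxia was called without BATF3 siRNA replicate 2, and plasma cell genes without it or without control siRNA replicate 3, both at the preset correlation. With all 6 arrays and an estimated correlation the adjusted p was 0.902 for hypoxia and 0.504 for plasma cell genes. Single genes changed sign with the most variable probe set (CD1D 0.011, EGLN3 −0.042, KRT18 0.12, TNRC6A −0.030), with array weights (CD1D 0.030) and with the background block (ERAP2 −0.049, NDUFB8 −0.082, TM7SF2 0.014). CD1D ran from −0.23 to 0.0055 with 1 array left out.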

Other observations

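Several genes outside the naming rule had small p-values in limma, and they were chosen here after their values were seen; none was called over all genes. PTPRC, which encodes the leukocyte phosphatase CD45, was at +0.92 (adjusted p = 0.184). Of its 6 probe sets 5 were higher, and 1 of them passed in the test per probe set at +1.05 (adjusted p = 0.0466). That probe set read 5.47 ± 0.063 after BATF3 siRNA and 4.42 ± 0.19 after control siRNA (SD, n = 3 each). In every array it lay under the highest background probe set. The bases of its probes were not examined, so the size of its change is uncertain. Among genes known to respond to interferon, IDO1 was at +0.57 and ETV7 at +0.71. INHBE, an activin subunit gene, was at +0.65 and ENTPD1, an ectonucleotidase gene, at +0.54. On the lower side, the cell cycle kinase gene CDK6 was at −0.58, the sphingosine 1-phosphate receptor gene S1PR1 at −0.77 and the integrin gene ITGA6 at −0.56. For the thyroid hormone receptor gene THRA the probe sets differed. One of its 8 probe sets was at −1.09 (adjusted p = 0.0193 in the test per probe set), and the others lay between −0.27 and −0.072.

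The tests of array background and of control siRNA replicate 2 were chosen after the list results were seen. Immediate early and ATF4 target genes were both higher as lists at the preset correlation, and neither was called with an estimated one (adjusted p = 0.0632 and 0.501). Their 65 members together had a mean of 0.220, and without control siRNA replicate 2, the array set apart by the first principal component, it was 0.213, which argues against that array as the whole source. The lower background of BATF3 siRNA replicates 2 and 3 may still contribute. BATF3 siRNA replicate 1, with the background of the controls, lay above the control mean by at least 8.28 control SDs in each list, and both lists stayed called at the preset correlation with the background as a block. That fit rests on the same single array, which cannot decide this, so background and siRNA cannot be told apart for these lists. A response to reduced BATF3, an effect of this siRNA on other transcripts and a difference in handling all stay open and were not tested.

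Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 3 genes and the highest of the others 0, so that 1 of the 10 splits gave as many. For gene lists, the real split called 4 and the highest of the others 8, and 3 of the 10 splits called at least as many. The split with 8 lists set both replicate 2 arrays and control siRNA replicate 1 against the rest, and the split with 7 set both replicate 2 arrays and control siRNA replicate 3 against the rest. At an unadjusted p under 0.05 the real split had 1304 genes and the highest of the others 1882, in the split of BATF3 siRNA replicates 2 and 3 with control siRNA replicate 2 against the rest. That split keeps both arrays of lower background on the same side. The fit with the background as a block had 1011, but it sets 1 BATF3 siRNA array against the controls with a further term, so that count is not comparable with these.

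Genes of cilia stood among those with the smallest p, chosen after their values were seen: CFAP57 at −0.71 (adjusted p = 0.0907), CLUAP1 at −0.66 (0.0907), CFAP263 at −0.70 (0.120) and CEP126 at −0.49 (0.310). A hypothesis was that ciliary genes fell more widely after BATF3 siRNA. A list of other ciliary genes was drawn up without these members before its value was computed. Its 86 measured genes had a mean of −0.0231, with 52 negative changes. None of them was called (7 lower and 4 higher at an unadjusted p under 0.05). Camera gave an adjusted p of 0.198, with this 1 list tested. Another split of the arrays gave a mean as far from 0 as 0.0323. A wider fall of ciliary genes was not seen, and the lower values of the 4 named genes stay unexplained.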
